A study of Mus musculus with 156 samples.

How the data were processed

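RNA was measured by SC3-Seq, an RNA sequencing method that reads the 3′ ends of transcripts, in 156 mouse libraries from 27 groups. Each of 65 libraries came from a single oocyte of a BDF1 mouse, and each of 47 from a pool of 10 to 20 granulosa or cumulus cells. A further 24 libraries were bulk samples of the H18 embryonic stem cell line, which carries Prdm1-EGFP and Dppa3-ECFP reporters, and of germ cells derived from it. The remaining 20 libraries came from single oocyte-like cells late in culture. The labels call the bulk samples biologically duplicated, and p-values from them measure the spread between these samples. In the culture, retinoic acid was given either until day 2.5 (short) or until the day of collection (extended), with BMP2 from day 3.

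The deposited files hold raw counts per gene on the mouse assembly GRCm38.p6, 1 file per library. The submitters' processing notes name cutadapt 1.18, TopHat2 2.1.1, Bowtie2 2.3.4.1 and HTSeq 0.11.0, without their order or options. Neither the strand setting nor the annotation release was available here, so reads of overlapping, antisense or closely related genes cannot be separated. Each file lists 35652 genes, of which 35642 held a value and were used. Symbol and span matched the RefSeq annotation of the same assembly for 90.91% of genes, and coordinates are printed as the files give them.

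Library totals ran from 972239 to 6813685 counts. Pearson's r of log2 values across genes between the bulk samples of 1 group ran from 0.969 in c13SChigh to 0.992 in c5. No 2 libraries of a group were closer than counting error, the lowest chi-square per degree of freedom being 2.54. Poisson 95% intervals and floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. A fold against a group with a count of 0 is given as a lower bound, from summed counts and a floor of 3 counts over the group.

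Single oocytes and granulosa pools were not treated as replicates, because the animals behind them were not known. Their counts were summed per stage and age label, which gave 16 sums in 8 groups of 2 (6 and 7 weeks) for the follicle stages from primordial to preantral. Antral, GV and MII oocytes, cumulus cells and the late culture groups carry no age label that splits them, so each counted as 1 sample. Pairs of such groups are described by CPM, the usual count scaled to the library total, of summed counts and have no test. For them, genes were named by size of change with a pseudocount of 1 CPM, a minimum of 100 CPM and up to 8 genes per direction. At least 75% of the libraries of the higher group had to lie above the other group.

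Genes were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM factors and the quasi-likelihood test on 14711 genes in the bulk fit, 16672 in the in vivo fit and 14849 in the fit of late culture cells against in vivo oocytes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 changes are standard errors (SE), computed as the size of the change over the square root of the F statistic. The common biological coefficient of variation was 0.16 in the bulk fit (12 residual degrees of freedom), 0.664 in vivo (8) and 0.48 for the late culture fit (5). The fit of late culture cells compared 3 sums (c24, c34, c34DBF1) with 4 sums of secondary and preantral oocytes. Lists of genes were tested with fry of limma 3.58.1, with adjustment over the lists of each comparison. This test asks whether the genes of a list move on balance one way, and compares the list with no other genes. The 33 gene lists, with 492 measured genes, the groups, the naming rule, the main alternatives and most comparisons were fixed before the data were examined. The comparisons of retinoic acid at single days and of the stage change between oocytes and granulosa cells were added later. Meiosin was read as Gm4969 and H1foo as H1f8.

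The naming rule took, in each tested comparison, up to 8 called genes per direction with the largest change. It required a mean of at least 20 CPM in the higher group and no overlap between the replicates of both sides, or for means over days or stages the same direction in each. Predicted, mitochondrial and ribosomal protein genes were left out. From each gene list described it took 2 to 4 members with the smallest adjusted p, and in every comparison the reporter genes Prdm1 and Dppa3. Levels printed beside tested genes are mean CPM with the TMM factors.

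The calling was tested on simulated counts, with 100 genes changed 2-fold and 100 changed 4-fold, all with a mean of at least 5 CPM. Counts were drawn from a negative binomial model in which each gene had the same mean in all groups apart from these changes. The spread followed the trend over expression, without the spread of single genes. The shares below therefore do not cover rarer genes or genes with an unusual spread. For c7 against c3 the test called 68% of the 2-fold and 94% of the 4-fold changes, with 6.36% false among all calls. For extended against short retinoic acid it called 86% and 100% (6.06% false), for secondary against primary oocytes 1% and 20% (12.5% false), and for late culture cells against in vivo oocytes 9% and 77% (1.15% false). The other in vivo stage steps were not simulated.

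Alternatives were DESeq2 1.42.0 tests, DESeq2 size factors in the edgeR fit, no filter on low counts, mitochondrial genes left out, and each replicate or sum left out in turn. Other alternatives took the replicate number or the age label as a block, left out library series MS378, thinned libraries to 972239 counts before summing, took each granulosa pool as a replicate, or used other in vivo classes. Added later were fits of oocyte or granulosa sums alone, and the same alternatives for the comparisons added later. Late culture cells were compared with in vivo stages by Pearson's r of log2 values with a pseudocount of 1 CPM over 10309 genes with a mean of at least 5 CPM. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The c5 group entered the bulk fit and no comparison. A few genes that the naming rule picked are not reported here.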

Results

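The libraries follow female germ cells of the mouse in the ovary and in culture. In vivo they hold single oocytes from primordial (9), primary (10), secondary (10), preantral (7) and antral (16) follicles, germinal vesicle (GV) oocytes (6) and metaphase II (MII) oocytes (7). Pools of granulosa cells came from primordial (6), primary (10), secondary (10) and preantral (6) follicles, and 15 pools of cumulus cells from antral follicles. In culture, 2 bulk samples each stood for embryonic stem cells (ESC), epiblast-like cells (EpiLC), and culture days 3, 5, 7, 9, 11 and 13 with short retinoic acid (c3 to c11 and c13SChigh). Another 2 each stood for days 7, 9, 11 and 13 with extended retinoic acid (RAc7 to RAc13). Single oocyte-like cells came from c24 (7), c34 (7) and c34DBF1 (6), a group whose suffix the labels do not explain. Median totals per group ran from 1788345 counts in c11 to 4393084 in c34.

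The step from ESC to EpiLC asks how the line left naive pluripotency before germ cell induction. Genes of the naive network were lower in EpiLC. The transcription factor gene Tfcp2l1 fell by 5.72 ± 0.28 on the log2 scale (SE, n = 2 bulk samples per group here and below), from 282 to 5.46 CPM. Esrrb, another regulator of naive cells, fell by 4.28 ± 0.30 and Zfp42, a naive marker, by 3.33 ± 0.18. Of the 14 measured naive genes 12 fell and 0 rose (12 and 0 adjusted over the list alone). Primed epiblast genes moved the other way. Pou3f1, a transcription factor of the primed epiblast, rose by 7.63 ± 0.45, the kinase gene Pim2 by 4.13 ± 0.30, and the de novo DNA methyltransferase genes Dnmt3b and Dnmt3a by 3.01 ± 0.23 and 2.53 ± 0.26. In that list 9 of 11 rose and 1 fell (9 and 1 adjusted over the list alone). Cholesterol synthesis genes rose in 12 of 19 cases and fell in 0 (12 and 0 adjusted over the list alone), as did 8 of 15 p53 targets with 0 lower (8 and 0 adjusted over the list alone). Jam2, which codes for a junctional adhesion protein (chromosome 16, 84774123 to 84826380), was listed at 0 in EpiLC and at 273 CPM in ESC, at least 500.1-fold lower. Limma's fry gave adjusted p = 3.2e-08 for the fall of the naive list and 1.4e-06 for the rise of the primed list, among 13 lists called of 31. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3312 genes (2126 higher, 1186 lower). The split depended on scaling, since DESeq2 size factors in the same test gave 1703 higher and 1547 lower and moved the median of all genes by -0.12. The changes named here were many times that shift. Without ESC replicate 2 the count was 1955.

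The comparison of c3 with EpiLC asks which genes marked the germ cells at culture day 3, which had received retinoic acid until day 2.5. Germ cell induction, culture and retinoic acid lie between these groups and cannot be told apart. Prdm1, the gene for a repressor that specifies germ cells and the host of the EGFP reporter, rose by 2.94 ± 0.26, from 11.8 to 86.8 CPM, with adjusted p = 4.7e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Dppa3, an early germ cell gene and the host of the ECFP reporter (chromosome 6, 122626424 to 122630271), rose by 4.30 ± 0.40, from 75.7 to 1518 CPM. The integrin gene Itgb3 stood at 35.1 CPM in c3 and 0.13 in EpiLC (1 count). The homeobox gene Rhox9 rose by 6.19 ± 0.36 and Dnd1, whose RNA-binding protein keeps germ cells alive, by 3.59 ± 0.34. Of 15 primordial germ cell genes 14 rose and 1 fell (14 and 1 adjusted over the list alone). Naive genes returned in 7 of 14 cases with 1 lower (8 and 1 adjusted over the list alone), led by Tcl1, a co-activator of Akt kinases, at 5.24 ± 0.32. Genes of the BMP response rose in 6 of 15 cases with 1 lower (6 and 1 adjusted over the list alone), among them Id3 (3.31 ± 0.19) and Gata2 (55.9 CPM in c3 and 0.249 in EpiLC), both transcriptional targets of BMP signals. Primed epiblast genes fell in 9 of 11 cases with 1 higher (9 and 1 adjusted over the list alone), and Pou3f1 fell by 8.10 ± 0.44. Genes of the amino acid and endoplasmic reticulum stress response fell in 12 of 16 cases and rose in 0 (14 and 0 adjusted over the list alone). Among them the serine synthesis gene Phgdh fell by 4.46 ± 0.27. Fgf4, which codes for a growth factor of pluripotent cells (chromosome 7, 144861386 to 144865245), was listed at 0 in c3 and at 155 CPM in EpiLC, at least 293.6-fold lower. Fry's adjusted p was 1.2e-07 for the rise of the germ cell list and 1.1e-07 for the fall of the primed list, among 15 lists called of 31. edgeR called 5655 genes (2852 higher, 2803 lower), and with DESeq2 size factors 2599 were higher and 3061 lower. EpiLC and c3 libraries belong to different library series, so batch and group cannot be told apart.

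From c3 to c7 the question is how meiosis started under BMP2 with short retinoic acid. Genes of meiotic prophase rose in 30 of 31 cases and fell in 0 (30 and 0 adjusted over the list alone). Sycp3, which codes for a protein of the chromosome axis, rose by 4.57 ± 0.22, from 12.9 to 308 CPM, and the meiotic cohesin genes Smc1b and Stag3 by 3.38 ± 0.17 and 2.82 ± 0.20. Stra8, the gene for a factor that starts meiosis (chromosome 6, 34920163 to 34939344), rose by 7.25 ± 0.51, from 1.31 to 204 CPM, with adjusted p = 2.1e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gm4969 (Meiosin), whose protein binds STRA8, went from 0.478 to 105 CPM. Prdm9, which codes for the histone methyltransferase that places meiotic breaks, went from 0.159 to 23.04 CPM. Later germ cell genes rose in 16 of 18 cases with 1 lower (17 and 1 adjusted over the list alone), among them Taf7l, a germ cell transcription factor subunit, which went from 0.327 to 129 CPM. In the piRNA list 12 of 16 rose and 1 fell (13 and 1 adjusted over the list alone), with the helicase gene Ddx4 at 2.80 ± 0.18 and Mael at 3.11 ± 0.23. Figla, a transcription factor gene of oocytes, was listed at 0 in c3 and at 20.2 CPM in c7, at least 52.1-fold higher. Retinoic acid response genes rose in 5 of 20 cases with 1 lower (5 and 1 adjusted over the list alone). The median of that list was -0.05, while fry called it higher (adjusted p = 0.0017). Cell cycle genes fell in 17 of 22 cases and rose in 0 (18 and 0 adjusted over the list alone), by small amounts such as 1.16 ± 0.20 for Tyms, which makes thymidylate. Prdm1 fell by 0.59 ± 0.22, and the change of Dppa3 (-0.73 ± 0.34) was not called (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, p = 0.13). For the meiotic list fry's adjusted p was 7.9e-10, among 25 lists called of 31. edgeR called 4704 genes (2560 higher, 2144 lower). The count was 3093 without c3 replicate 1 and 2904 without c3 replicate 2. Without both libraries of series MS378 (c7 replicate 2 and c11 replicate 2) 3250 genes were called, of which 3161 were shared.

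From c7 to c11 the comparison follows cells through prophase and into early oocyte programs. The meiotic list rose further, with 27 of 31 higher and 2 lower (27 and 2 adjusted over the list alone). Sycp2, another axis gene, rose by 3.76 ± 0.19, from 37.8 to 511 CPM, and Tex15, a germ cell gene of the piRNA and recombination machinery, by 3.19 ± 0.18. Stra8 fell by 3.24 ± 0.36, from 204 to 21.4 CPM. Oocyte transcription factor genes rose in 7 of 10 cases with 1 lower (7 and 1 adjusted over the list alone). Sohlh1 rose by 4.90 ± 0.37, Figla by 3.47 ± 0.24 and Lhx8 by 6.66 ± 0.68, all regulators needed for primordial follicles, and Nobox went from 0.228 to 46.4 CPM. The earlier program was lower. Primordial germ cell genes fell in 14 of 15 cases and rose in 0 (14 and 0 adjusted over the list alone), among them Prdm1 by 2.85 ± 0.30 and Dnd1 by 4.13 ± 0.43. General pluripotency genes fell in 9 of 10 cases and rose in 0 (9 and 0 adjusted over the list alone), with Pou5f1, the central pluripotency factor (chromosome 17, 35506032 to 35510777), from 149 to 2.48 CPM. Cell cycle genes fell in 17 of 22 cases and rose in 1 (17 and 1 adjusted over the list alone), for example the mitotic cyclin gene Ccnb1 by 3.10 ± 0.23. Dppa3 fell by 3.04 ± 0.39, from 917 to 112 CPM. Stroma and fibroblast genes rose in 4 of 18 cases (2 adjusted over the list alone) with 0 lower, including the collagen gene Col1a2 at 2.66 ± 0.67, and fry did not call that list (adjusted p = 0.17). The meiotic and the oocyte transcription factor list each had adjusted p = 1.8e-08 from fry, among 16 lists called of 31. edgeR called 6429 genes (3219 higher, 3210 lower). DESeq2 size factors moved the median of all genes by 0.12 and gave 3661 higher and 2798 lower. Without c11 replicate 1 the count was 4003, and without both MS378 libraries 4440 genes were called, 4236 of them shared.

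The comparison of c13SChigh with c11 asks what distinguished the day 13 cells sorted for high reporter signal. Genes of the subcortical maternal complex, a protein assembly of the egg cortex, rose in 6 of 7 cases and fell in 0 (6 and 0 adjusted over the list alone). Padi6 (chromosome 4, 140727355 to 140742643) rose by 5.94 ± 0.39, from 4.05 to 234 CPM, with adjusted p = 1.5e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tle6 and Ooep of the same complex rose by 2.69 ± 0.26 and 2.69 ± 0.27. Oocyte growth genes rose in 11 of 16 cases and fell in 0 (12 and 0 adjusted over the list alone). Among them were Zp3, which codes for a protein of the egg coat (5.50 ± 0.54), and Gdf9, an oocyte growth factor (3.39 ± 0.44). Oocyte transcription factor genes rose in 8 of 10 cases and fell in 2 (8 and 2 adjusted over the list alone), with Trp63, the p53 relative that guards oocytes, at 4.98 ± 0.56. Foxo3, whose protein holds primordial follicles at rest, rose by 2.31 ± 0.23, in a list of primordial follicle arrest with 4 of 10 higher and 0 lower (4 and 0 adjusted over the list alone). Kdm1b, a histone demethylase gene of growing oocytes, rose by 3.29 ± 0.20. Meiotic prophase genes fell in 25 of 31 cases and rose in 0 (26 and 0 adjusted over the list alone), for example Hormad2, a monitor of unsynapsed axes, by 2.62 ± 0.23. Dppa3, whose reporter the gate used, rose by 3.89 ± 0.40, from 112 to 1658 CPM. Cells at c11 were not sorted by that gate, so sorting and day cannot be told apart for any change in this comparison. Adjusted p from fry was 4.4e-07 for the maternal complex list and 4.6e-07 for the meiotic list, among 17 lists called of 31. edgeR called 4168 genes (2200 higher, 1968 lower), and DESeq2 size factors turned the split to 1938 higher and 2286 lower. Without c11 replicate 1 the count was 2443, and without both MS378 libraries it was 3183, with 2918 shared.

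**Figure D1:**
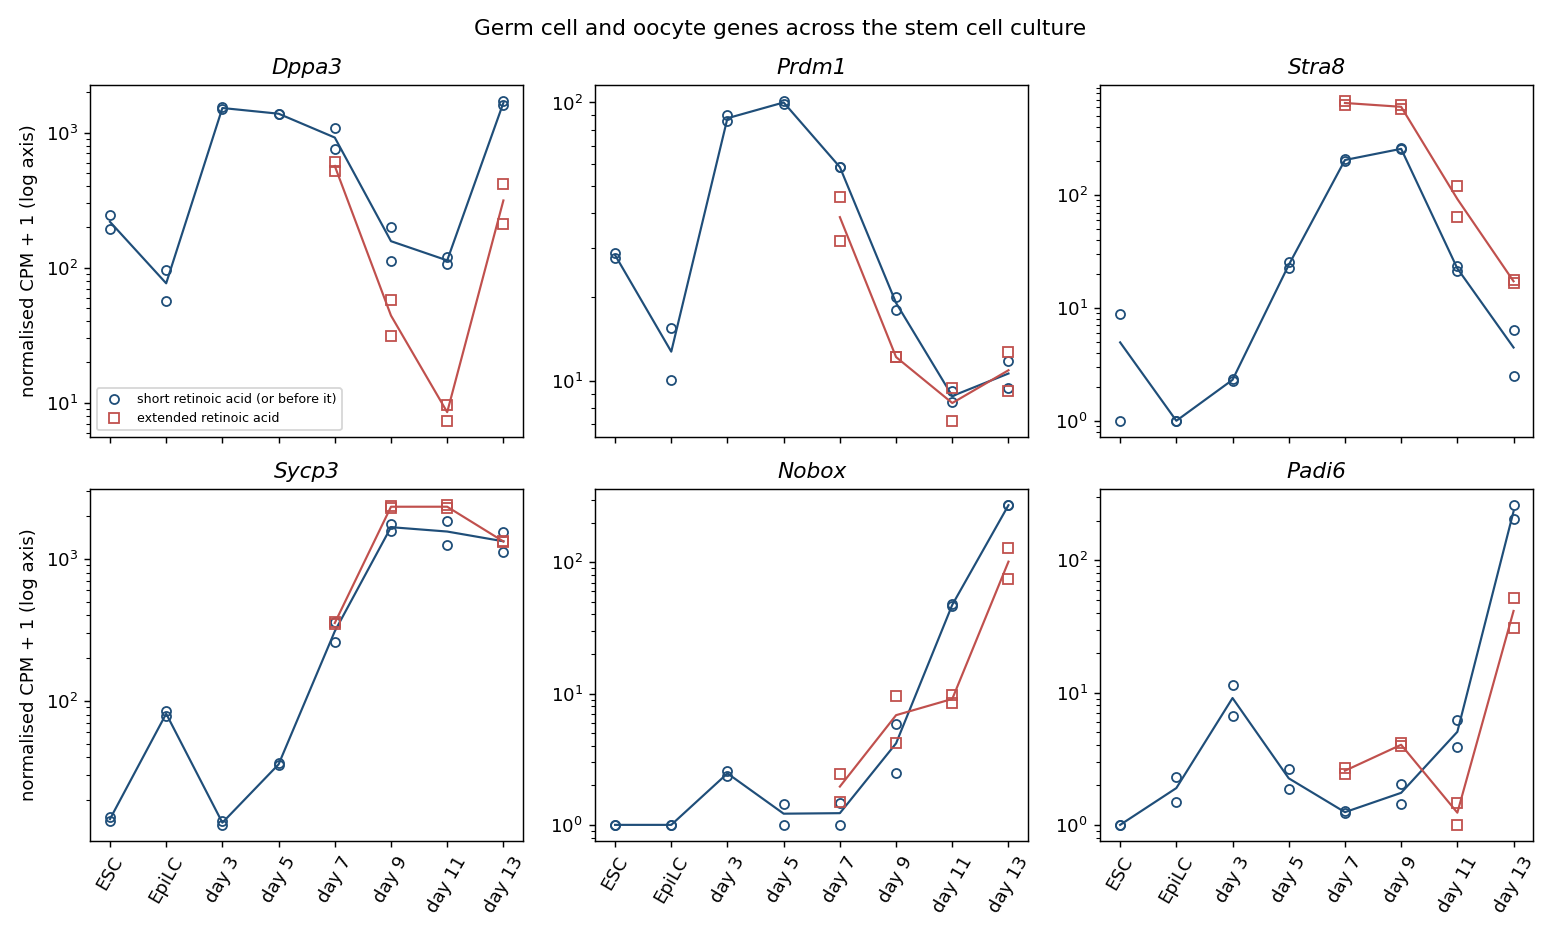
Normalised CPM plus 1 on a log axis for 6 genes by culture step, with points for the 2 bulk samples of each group, lines through means, and blue for short and red for extended retinoic acid. Dppa3 stood at 1518 CPM in c3, 112 in c11 and 1658 in c13SChigh, while Padi6 was at 4.05 in c11 and 234 in c13SChigh.

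Extended against short retinoic acid asks what longer exposure changed at days 7, 9 and 11. Averaged over these days, genes of the retinoic acid response were higher, 11 of 20 with 0 lower (14 and 0 adjusted over the list alone). Dhrs3, whose enzyme reduces retinal, rose by 3.10 ± 0.32, with adjusted p = 4.9e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cyp26a1, whose enzyme breaks down retinoic acid (chromosome 19, 37697738 to 37701536), rose by 4.08 ± 0.69, the homeobox gene Hoxa5 by 4.43 ± 0.62 and the receptor gene Rarb by 2.32 ± 0.39. Stra8 rose by 1.68 ± 0.18, from 161 to 452 CPM. Meiotic genes rose in 10 of 31 cases and fell in 0 (12 and 0 adjusted over the list alone), by less than Stra8, for example Meioc, a partner in prophase entry, by 0.89 ± 0.13. Naive pluripotency genes fell in 6 of 14 cases and rose in 0 (10 and 0 adjusted over the list alone), and Tcl1 fell by 2.67 ± 0.24. General pluripotency genes fell in 6 of 10 cases and rose in 0 (9 and 0 adjusted over the list alone), and Sox2 fell by 2.86 ± 0.53. At single days Sox2, Pou5f1 and Nanog were called lower at day 9 only, Sox2 by 3.10 ± 0.60 there. Dppa3 fell by 2.17 ± 0.25. The granulosa list rose in 2 of 13 cases with 0 lower (3 and 0 adjusted over the list alone), through Wt1 (3.26 ± 0.49) and Kitl (1.31 ± 0.38). Adjusted p from fry was 9.4e-06 for the retinoic acid list and 0.00028 for the meiotic list, among 11 lists called of 31. edgeR called 881 genes (410 higher, 471 lower), of which 273 changed at least 2-fold. DESeq2 size factors turned the split to 473 higher and 408 lower. Since c7 replicate 2 and c11 replicate 2 came from series MS378, the fit was repeated without both and called 379 genes, 352 of them shared. Leaving out 1 library gave 575 (c7 replicate 2), 457 (c9 replicate 2), 531 (c11 replicate 2), 485 (RAc7 replicate 2), 520 (RAc9 replicate 1 and likewise RAc11 replicate 1) or 572 (RAc9 replicate 2).

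Day by day, the retinoic acid list was higher with extended exposure at day 7 in 7 of 20 cases (10 adjusted over the list alone), at day 9 in 3 (9 adjusted over the list alone) and at day 11 in 3 (6 adjusted over the list alone), with 0 lower at each day. Cyp26a1 stood at 114 CPM in RAc7 and 0.248 in c7. Stra8 was at 607 CPM in RAc9 and 257 in c9. At day 11 oocyte transcription factor genes were lower, 4 of 10 with 0 higher (4 and 0 adjusted over the list alone). Sohlh1 (chromosome 2, 25842995 to 25847248) fell by 3.06 ± 0.32, from 71.03 CPM in c11 to 7.95 in RAc11, Lhx8 by 2.91 ± 0.49, Nobox by 2.48 ± 0.42 and Figla by 0.91 ± 0.22. The piRNA gene Tdrd1, a Tudor domain gene, fell by 2.60 ± 0.28, in a list with 3 of 16 lower and 0 higher (3 and 0 adjusted over the list alone). Dppa3 was at 7.54 CPM in RAc11 and 112 in c11. The effect of extended exposure differed between days for 25 genes, among them Sohlh1 (adjusted p = 7.1e-05), Pramef12, a germ cell gene of the Prame family (9.3e-07), and Nobox (0.039), and was not called for Dppa3 (0.15), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That count was 13 without the MS378 libraries, with 8 shared. It was 14 without c7 replicate 1, 59 without c9 replicate 1, 12 without c11 replicate 2, 8 without RAc7 replicate 1, 9 without RAc7 replicate 2, 16 without RAc9 replicate 2, 5 without RAc11 replicate 1 and 8 without RAc11 replicate 2, and it equalled 13 without c7 replicate 2.

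For single days edgeR called 40 genes at day 7 (31 higher, 9 lower), 249 at day 9 (61 higher, 188 lower) and 263 at day 11 (120 higher, 143 lower). With DESeq2 size factors the day 11 split was 151 higher and 138 lower. Adjusted p from fry for the retinoic acid list was 0.00031 at day 7, 0.0026 at day 9 and 0.00096 at day 11, and for the oocyte transcription factor list 0.0003 at day 11. Without 1 library the day 7 count was 7 (c7 replicate 1), 5 (c7 replicate 2), 9 (RAc7 replicate 1) or 6 (RAc7 replicate 2). The day 9 count was 399 (c9 replicate 1), 25 (c9 replicate 2), 35 (RAc9 replicate 1) or 43 (RAc9 replicate 2). The day 11 count was 151 (c11 replicate 1), 80 (c11 replicate 2), 52 (RAc11 replicate 1) or 85 (RAc11 replicate 2). Leaving out both MS378 libraries left 5 genes at day 7 and 72 at day 11, of which 5 and 60 were shared.

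**Figure D2:**
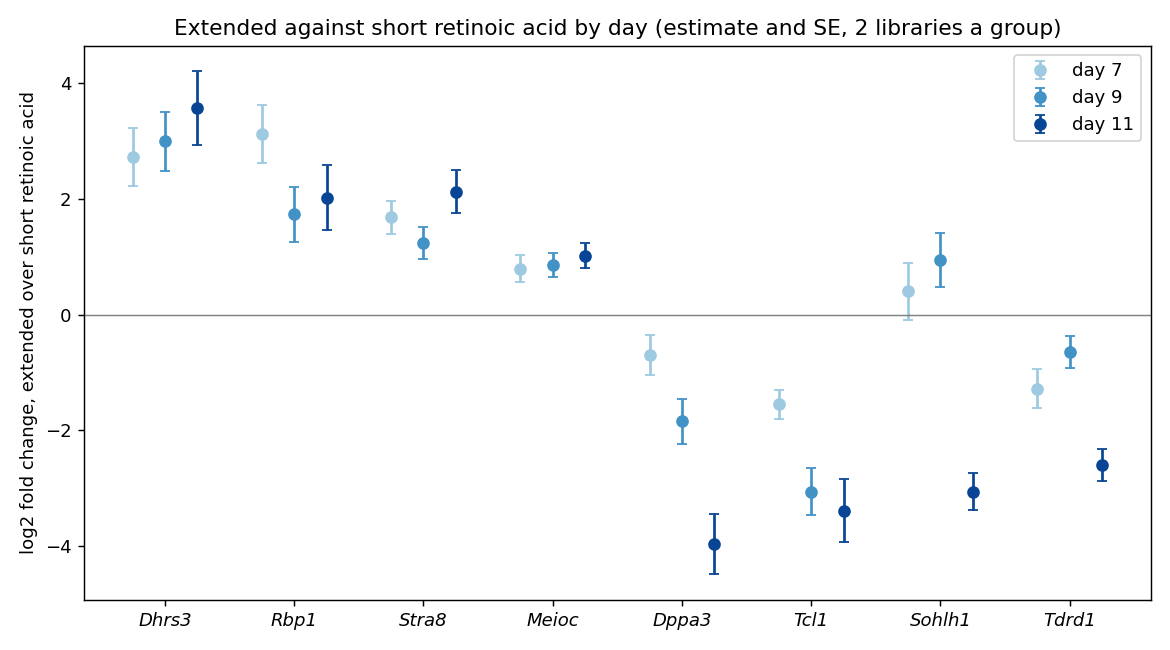
Log2 change with its SE, extended over short retinoic acid, for 8 genes at days 7, 9 and 11 (2 bulk samples a group). Sohlh1 changed by -3.06 ± 0.32 at day 11.

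At day 13 the extended and short conditions were also sorted by different gates (SC+ for RAc13, SC high for c13SChigh), so exposure and gate cannot be told apart. Oocyte programs were lower in RAc13. All 7 measured genes of the subcortical maternal complex fell (7 adjusted over the list alone), Padi6 by 2.54 ± 0.28. Oocyte growth genes fell in 13 of 16 cases and rose in 0 (14 and 0 adjusted over the list alone), among them Zp3 by 4.12 ± 0.44 and H1f8, the oocyte linker histone gene, by 3.61 ± 0.50. Oocyte transcription factor genes fell in 8 of 10 cases and rose in 2 (8 and 2 adjusted over the list alone). Genes of other lineages were higher. Somatic lineage genes rose in 8 of 10 cases and fell in 0 (8 and 0 adjusted over the list alone), with the keratin gene Krt18 at 4.50 ± 0.46 and Gata4, a factor of endoderm and gonadal soma, at 4.18 ± 0.93. Sox17, an endoderm and germ cell factor (chromosome 1, 4490928 to 4497426), was at 25.3 CPM in RAc13 and listed at 0 in c13SChigh, at least 53.5-fold higher. Genes of the BMP response rose in 9 of 15 cases (13 adjusted over the list alone) with 0 lower, Gata2 by 2.77 ± 0.21. Retinoic acid response genes rose in 12 of 20 cases and fell in 0 (16 and 1 adjusted over the list alone), and meiotic genes rose in 15 of 31 cases and fell in 1 (15 and 1 adjusted over the list alone), Meioc by 2.29 ± 0.23. Dppa3 fell by 2.41 ± 0.36, from 1658 to 313 CPM. Adjusted p from fry was 2.4e-06 for the maternal complex and BMP lists alike, among 18 lists called of 31. edgeR called 3317 genes (1599 higher, 1718 lower), which DESeq2 size factors turned to 1712 higher and 1603 lower. The count was 1938 without c13SChigh replicate 2 and 1476 without RAc13 replicate 1.

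In vivo, the step from primordial to primary follicles asks which oocyte genes came up as growth began. Npm2, the gene for the egg chaperone nucleoplasmin (chromosome 14, 70647296 to 70661802), rose by 7.08 ± 1.32, from 1.33 to 236 CPM (n = 2 sums per stage), with adjusted p = 0.03 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gdf9 rose by 1.80 ± 0.35 to 801 CPM and Oosp1, a secreted oocyte protein gene, by 5.37 ± 1.06. Id1, a BMP target gene, fell by 5.30 ± 0.91, from 66.3 to 1.67 CPM. Oocyte growth genes rose in 3 of 21 cases and fell in 0 (7 and 0 adjusted over the list alone). Fry did not call that list (adjusted p = 0.34). For this step fry called 0 of 32 lists (6 had an unadjusted p under 0.05), and edgeR called 142 genes (118 higher, 24 lower). Single sums decided that count, which was 1535 without the 6 week primordial sum, 73 without the 7 week primordial sum, which is 1 oocyte, and 27 without the 6 week primary sum.

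From primary to secondary follicles Gdf9 rose further, by 2.41 ± 0.36 to 4255 CPM, and Bmp15, its partner in follicle growth, rose by 3.99 ± 0.91 from 44.7 to 710.1 CPM. The homeobox genes Obox1 (chromosome 7, 15547257 to 15556846) and Obox5 rose by 9.41 ± 1.02 and 7.82 ± 1.12. Evx1, another homeobox gene, was listed at 0 in primary and at 44.9 CPM in secondary oocytes, at least 352.9-fold higher. The amino acid transporter gene Slc38a1 fell by 5.15 ± 0.89. Genes of the maternal complex rose in 3 of 8 cases with 0 lower (4 and 0 adjusted over the list alone), among them Zbed3 at 3.52 ± 0.45. Oocyte growth genes rose in 3 of 21 (8 adjusted over the list alone) and oocyte maturation genes in 3 of 22 (7 adjusted over the list alone), with 0 lower in both. Fry's adjusted p was 0.063 for the maternal complex and 0.11 for the growth list, and fry called 0 of 32 lists (12 had an unadjusted p under 0.05). edgeR called 344 genes (200 higher, 144 lower). The count was 199 without the 6 week primary sum, 11 without the 7 week primary sum, 183 without the 6 week secondary sum and 35 without the 7 week secondary sum.

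Between secondary and preantral oocytes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2 genes, of 1217 with an unadjusted p under 0.05, whereas the DESeq2 Wald test called 263. Maged1, a gene of the melanoma antigen family (chromosome X, 94535474 to 94542025), fell by 2.67 ± 0.26, from 443.5 to 69.6 CPM (adjusted p = 0.0013). The calcium pump gene Atp2b4 rose by 5.54 ± 0.69 (adjusted p = 0.014), a gene outside the naming rule that was chosen after its values were seen. The count was 0 without the 6 week secondary sum, when Maged1 and Atp2b4 were both no longer called, 1 without the 7 week secondary sum and 4 without the 6 week preantral sum. Fry called 0 of 32 lists for this step, and 4 had an unadjusted p under 0.05.

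For granulosa cells, the comparison of preantral with primordial follicles asks what changed as the layer around the oocyte grew. Cell cycle genes were higher, 9 of 22 with 0 lower (16 and 0 adjusted over the list alone). Aurkb and Aurka, mitotic kinase genes, rose by 6.24 ± 0.87 and 3.89 ± 0.58, and the cyclin gene Ccna2 rose by 5.47 ± 0.93, from 1.76 to 83.5 CPM. Cenpf, a kinetochore gene (chromosome 1, 189640606 to 189688107), was listed at 0 in primordial granulosa cells and at 78.8 CPM in preantral ones, at least 355.9-fold higher. Aldh1a2, whose enzyme makes retinoic acid, was listed at 0 in preantral and at 110.3 CPM in primordial granulosa cells, at least 565.9-fold lower. Stress response genes fell in 3 of 16 cases with 0 higher (4 and 1 adjusted over the list alone), including Atf4, the factor that drives that response, by 1.24 ± 0.28. The fry test gave adjusted p = 0.013 for the cell cycle list and 0.043 for the stress list, the 2 lists called of 32. Germ cell transcripts differed between these pools too. Dppa3 fell by 4.67 ± 0.67, from 75.5 to 3.28 CPM, and oocyte transcription factor genes fell in 2 of 11 cases with 0 higher (4 and 0 adjusted over the list alone), a list that fry did not call (adjusted p = 0.28). Stroma and fibroblast genes rose in 1 of 17 cases and fell in 1 (1 and 3 adjusted over the list alone), with fry's adjusted p at 0.50. RNA of oocytes or stroma in the pools cannot be separated from a change in granulosa cells. edgeR called 454 genes (263 higher, 191 lower). That split did not hold in each setting, since DESeq2 size factors gave 251 higher and 250.0 lower, each pool taken as a replicate 348 and 433, and the granulosa sums fitted alone 166 and 214. Without 1 sum the count was 862 (6 week primordial), 683 (7 week primordial), 291 (6 week preantral) or 244 (7 week preantral).

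Oocytes were set against the granulosa cells of the same 4 stages to show which genes separated both partners of the follicle. Granulosa genes were lower in oocytes in 20 of 21 cases and higher in 0 (20 and 0 adjusted over the list alone), for example Amhr2, the receptor gene for anti-Müllerian hormone, at 0.409 against 437 CPM, a log2 change of -10.02 ± 0.38 (n = 8 sums per cell type). Growth and egg coat genes were higher, 20 of 21 with 0 lower (20 and 0 adjusted over the list alone), with Gdf9 at 7.13 ± 0.22 and the coat gene Zp1 at 10.42 ± 0.35. All 8 measured genes of the maternal complex were higher (8 adjusted over the list alone), Khdc3 by 9.40 ± 0.33. Of 18 piRNA genes 16 were higher and 0 lower (16 and 0 adjusted over the list alone), among them Ddx4. Wnt4 and Wnt6, ligand genes on the list for flat pregranulosa cells, fell by 9.02 ± 0.27 and 10.62 ± 0.36, and 5 of 8 genes of that list were lower with 0 higher (5 and 0 adjusted over the list alone). Genes of the immediate early and heat shock list, such as Fosb (-8.49 ± 0.27), were lower in oocytes in 12 of 15 cases and higher in 1 (12 and 1 adjusted over the list alone). The lactate dehydrogenase genes parted, with Ldha at -7.59 ± 0.54 and Ldhb at 1.34 ± 0.11. With fry the adjusted p was 8.9e-10 for the granulosa list and 5.6e-10 for the piRNA list, among 27 lists called of 32. edgeR called 9765 genes (4979 higher, 4786 lower). Size factors of DESeq2 turned the split to 4736 higher and 5042 lower and moved the median of all genes by -0.10, far less than the changes named.

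The change from primordial to preantral follicles differed between oocytes and granulosa cells for 1995 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (983 with a higher change in oocytes, 1012 with a lower change). For Gdf9 the difference of both log2 changes was 4.37 ± 0.52, for the protease inhibitor gene Serpine2 it was 7.93 ± 0.51, and for Aurkb it was -7.64 ± 1.09. Oxidative phosphorylation genes had a lower change in oocytes than in granulosa cells in 11 of 26 cases and a higher one in 0 (15 and 0 adjusted over the list alone), including the ATP synthase gene Atp5o at -2.55 ± 0.30, and fry's adjusted p was 0.0022. DESeq2 size factors gave 2003 genes (1165 and 838) and moved the median of all genes by 0.23, and each of these differences was larger than that. The count was 1035 without the 6 week preantral oocyte sum and 965 without the 7 week one.

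Later in vivo stages had 1 sample each, and their values carry Poisson intervals for counting error only. Antral and preantral oocytes belong to different library series, as do GV and antral oocytes and cumulus and preantral granulosa cells, so batch and group cannot be told apart in these 3 pairs. Dab2, an endocytic adaptor gene, stood at 110 CPM in antral and 7.28 in preantral oocytes. Id3 fell from 156 (151 to 161) to 4.21 (3.63 to 4.85) CPM and Dppa5a, a gene of pluripotent and germ cells, from 2697 to 467. GV oocytes held 1322 (1306 to 1338) CPM of Plat, the tissue plasminogen activator gene, against 678 (671 to 686) in antral oocytes, and 229 CPM of Cflar, an inhibitor of cell death, against 414. In cumulus cells Inhba, the gene of an activin subunit, was at 534 (528 to 540.0) CPM and was listed at 0 in preantral granulosa cells, at least 3054-fold lower there. The SD between the 15 cumulus pools was 891 CPM, more than their value, so the level of Inhba was very uneven between pools. The rule for genes named by size required most cumulus pools to lie above the preantral granulosa pools. The glutamine transporter gene Slc38a5 stood at 572 CPM in cumulus cells and 4.31 in preantral granulosa cells. Wnt4 was at 12.6 and 469 CPM in the same order, and the basement membrane gene Col18a1 at 0.502 and 613.

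GV and MII oocytes share a library series, and their comparison asks which transcripts rose or fell in share through meiotic maturation. Obox5 was at 3317 (3295 to 3339) CPM in MII and 883 (870.0 to 895) in GV oocytes, and Obox2 at 2926 and 763 CPM. Tfdp1, the gene for a partner of E2F factors, was at 350.3 CPM in MII against 89.9 in GV. Chchd2, a nuclear gene for a mitochondrial protein, fell from 746 (735 to 758) to 9.71 (8.57 to 11.0) CPM, the translation factor gene Eif3m from 265 to 2.29 and Lrrc36 from 248 to 1.29. CPM are shares of a library, so a rise among fewer transcripts in all cannot be read as synthesis.

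The sums of late culture cells (c24, c34, c34DBF1) were set against secondary and preantral oocytes to ask where cultured oocyte-like cells differed from growing oocytes in vivo. No library series holds both, so batch and group cannot be told apart. The 3 culture sums are different groups and not replicates of 1 condition. The p-values therefore do not measure a spread between repeats of the same culture. Taken over the 3 sums, stress response genes were higher in culture, 10 of 16 with 0 lower (12 and 0 adjusted over the list alone). Among them were Asns, which makes asparagine, at 3.18 ± 0.54, and Shmt2, a mitochondrial serine enzyme gene, at 1.42 ± 0.18 (n = 3 against 4 sums). The groups differed, since the list total was 3.02 times the mean of secondary and preantral oocytes in c24, 2.58 in c34DBF1 and 1.37 in c34. Fgf21, a stress-induced hormone gene (chromosome 7, 45613890 to 45615490), stood at 82.4 CPM in culture and was listed at 0 in vivo, at least 1399-fold higher. The keratin gene Krt79 rose by 6.01 ± 0.59, from 2.58 to 165 CPM, with adjusted p = 0.0064 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Prdm1 was higher by 4.50 ± 0.95 and the difference of Dppa3 (-0.44 ± 0.22) was not called. The line of the bulk samples carries reporters of both genes, while the in vivo oocytes came from BDF1 mice. Where late culture cells share that line, genotype and culture cannot be told apart for these genes. Genes of the maternal complex fell in 2 of 8 cases and rose in 0 (7 and 0 adjusted over the list alone), Ooep from 7793 to 2346 CPM. Later germ cell genes fell in 4 of 16 cases and rose in 1 (8 and 2 adjusted over the list alone), Ddx4 by 1.13 ± 0.19. Id1 and Id2 of the BMP response rose by 3.70 ± 0.52 and 3.05 ± 0.69, with 2 of 12 genes higher and 1 lower (2 and 1 adjusted over the list alone). The granulosa list moved both ways, 1 higher and 2 lower of 14 (3 and 4 adjusted over the list alone), and was not called (fry's adjusted p = 0.71). Adjusted p from fry was 0.048 for the stress list and 0.029 for the maternal complex, among 5 lists called of 32. edgeR called 1460 genes (925 higher, 535 lower). The count was 338 without the 7 week secondary sum, 358 without the 6 week preantral sum, 467 without c34 and 579 without c34DBF1. Against preantral and antral oocytes it was 654 (377 higher, 277 lower), and against primary to preantral oocytes 838.

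Within late culture, c24, c34 and c34DBF1 had 1 sample each and came from different library series, so batch and group cannot be told apart. Nfkbiz, a regulator of NF-kB targets, was at 173 (168 to 178) CPM in c34 and 8.22 (6.83 to 9.81) in c24, and Bmp5, a growth factor gene, at 109 and 13.9 CPM. The chaperone gene Hspa5 fell from 761 CPM in c24 to 59.2 in c34, and the stress genes Herpud1 and Chac1 from 365 to 37.3 and from 136 to 11.8. The oocyte factor genes Sohlh1 and Tbpl2 fell from 187 to 12.6 and from 103 to 8.78 CPM. In c34DBF1 the stress genes stood high again, with Herpud1 at 504.3 CPM, Chac1 at 131 and Psat1, a serine synthesis gene, at 105. Atf3, a stress-induced factor, stood at 126.2 (121 to 131) against 5.88 (5.04 to 6.81) in c34. These levels were uneven between cells. The SD between c34DBF1 cells was 294 CPM for Herpud1, 87.1 for Chac1, 43.9 for Psat1 and 72.8 for Atf3. Between c24 cells it was 377 CPM for Hspa5, 289 for Herpud1 and 93.05 for Chac1. Tpi1, a glycolysis gene, was at 13.4 CPM in c34DBF1 and 187 in c34, and Oosp3, a secreted oocyte protein gene, at 43.2 and 503.

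The nearest in vivo stage of each late cell was read from Pearson's r across 10309 genes, which are not independent replicates. All 7 c24 cells lay nearest to preantral oocytes, with a mean r of 0.895 ± 0.0085 (SD, n = 7). Of the c34 cells 5 lay nearest to antral, 1 to GV and 1 to preantral oocytes, with a mean r of 0.889 ± 0.0073 (SD, n = 7) for antral and 0.886 ± 0.0083 for GV. Within cells, r was higher with antral than with GV oocytes in 6 of 7. The c34 cell nearest to preantral oocytes is replicate 1, the only one of series MS330, so series and nearest stage coincide there. All 6 c34DBF1 cells lay nearest to preantral oocytes, with a mean r of 0.845 ± 0.017 (SD, n = 6). With a minimum of 50 CPM, 6 c24 and 5 c34DBF1 cells lay nearest to preantral oocytes, and 1 of each to secondary oocytes. With Spearman's correlation 4 c34 cells lay nearest to antral, 2 to GV and 1 to preantral oocytes. Both c13SChigh samples lay nearest to primordial oocytes (mean r 0.821), as did both RAc13 samples (0.761). The samples of c3 (0.692), c5 (0.701), c7 (0.721), c9 (0.715) and c11 (0.730) also lay nearest to primordial oocytes, so the nearest stage does not set day 13 apart.

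**Figure D3:**
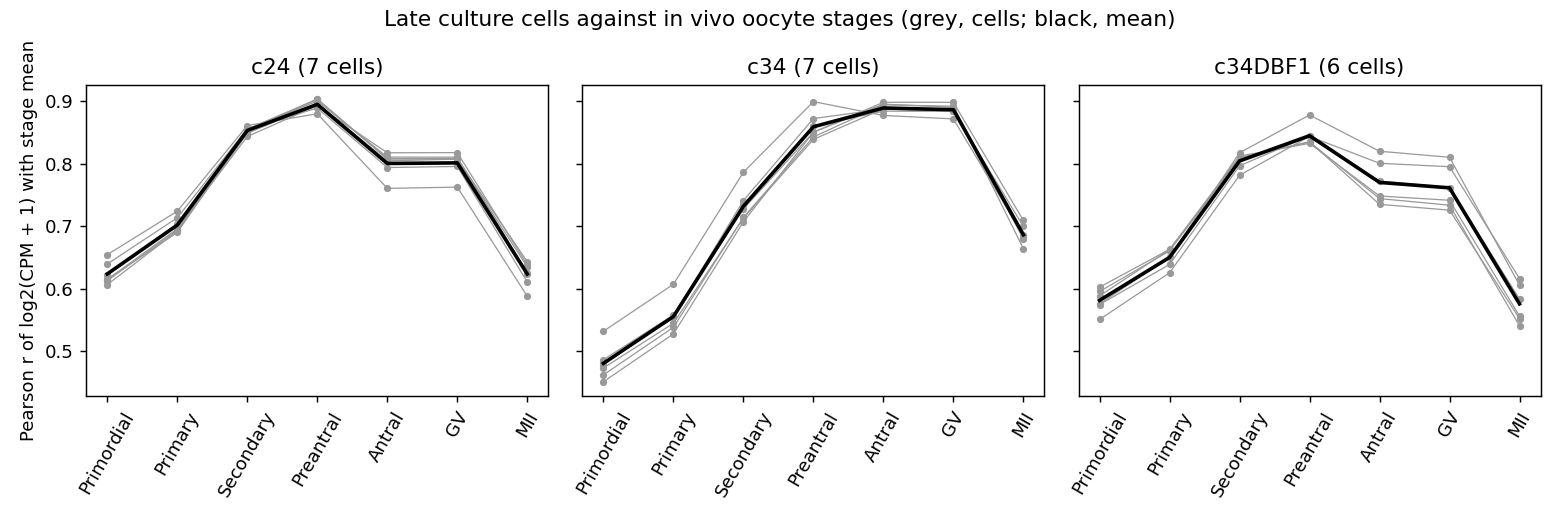
Pearson's r of log2 values between each late culture cell and the mean of each in vivo oocyte stage, with a grey line per cell and a black line for the mean. The mean r was highest with preantral oocytes in c24 (0.895) and c34DBF1 (0.845), and with antral oocytes in c34 (0.889).

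The 13 mitochondrially encoded protein genes took a falling share of counts from primordial to antral oocytes. The median share was 5.29% in primordial, 3.81% in primary, 2.24% in secondary, 1.32% in preantral and 0.547% in antral oocytes, and it was higher again at 0.704% in GV and 2.43% in MII oocytes. It was 1.36% in c24, 0.290% in c34 and 0.0396% in c34DBF1 cells. These shares were not tested.

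**Figure D4:**
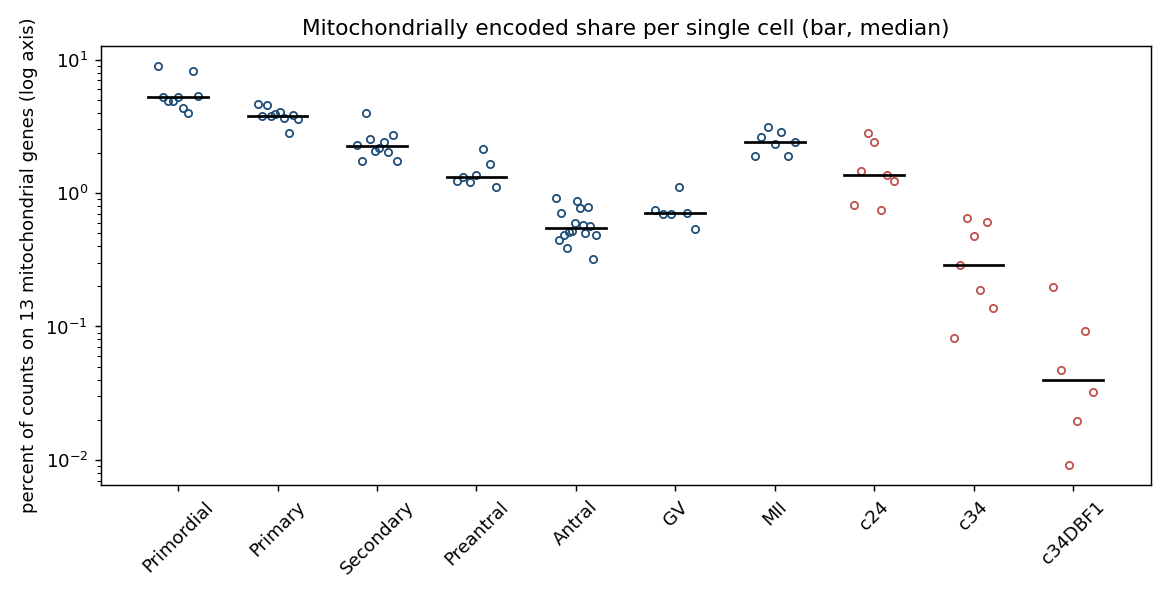
Percent of counts on 13 mitochondrially encoded genes per single cell on a log axis, with circles for cells and bars for medians. Medians fell from 5.29% in primordial to 0.547% in antral oocytes and stood at 0.0396% in c34DBF1 cells.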

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

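Among the tests below, the share of genes with the same sign at day 9 and the stress list ratio of series MS378 were set before their results were seen, and the other tests were chosen only after the result was seen.

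The effect of extended retinoic acid differed between days for 25 genes, a difference that 5 of 30 splits of the libraries within days also reached, with up to 102 genes in another split. The higher count of another split points to a structure of the samples, which exposure itself can supply. A split that keeps the labels at 1 day and exchanges them at another turns the mean effect into a difference between days, so the number of such splits does not decide whether chance can be excluded. For the mean effect over days 7, 9 and 11, 1 of 30 splits, the real one, reached 881 genes, and the highest other split gave 27. Splits that mix extended and short libraries within a day put their difference into the spread and lower the count. The low counts of the other splits therefore do not decide about chance here either.

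Libraries of series MS378 stood on the short side only, at days 7 and 11, and could have made part of the extended retinoic acid effect. Of 291 genes called at day 7 or 11, 238 (81.79%, exact 95% interval 76.86% to 86.05%) kept their sign at day 9, where no library comes from that series, against 61.75% of all genes between days 9 and 11 and 58.64% between days 7 and 9. That interval takes genes as independent, which genes of the same libraries are not, so it is too narrow, and it reaches below the 80% set beforehand. The share of signs therefore does not decide on the series. Without its libraries genes were still called at days 7 and 11, which argues against the series as the whole cause, while part of the effect may still follow it. The median signed change was 1.29 at the gene's own day and 0.387 at day 9. Genes picked for a call at 1 day tend to show smaller changes at another, so this drop does not decide on the series. A larger share of stromal cells in the extended cultures stays open. The stroma and fibroblast list was not called (fry's adjusted p = 0.147), which does not exclude such a share, and 1 of its 18 genes was higher with 0 lower (4 and 1 adjusted over the list alone), Loxl1 by 1.49 ± 0.32. At day 9 Tagln and Loxl1 were higher by 2.24 ± 0.56 and 2.13 ± 0.54, 2 of 18 with 0 lower (4 and 0 adjusted over the list alone). Other mesenchymal genes, chosen after their values were seen, were higher at day 9 too, among them Des by 2.35 ± 0.40, Fstl1 by 2.14 ± 0.37 and Mgp by 3.84 ± 0.97. At day 11 Des was higher by 2.24 ± 0.455, while Fstl1, Mgp, Tagln and Loxl1 were not called. Longer exposure itself, the difference the design names, also stays open.

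In c34DBF1 cells the mitochondrially encoded genes took a median of 0.0396% of counts, against 1.32% in preantral oocytes. A loss in all libraries of series MS378 is argued against by its bulk libraries, whose mitochondrial share was 0.993 of that of the other library in c7 and 0.7995 in c11. A loss limited to the single cells of that series would not show in bulk libraries, so the series stays open for these cells. A loss of a few abundant transcripts is argued against because 13 of 13 genes were lower in c34DBF1 than in preantral oocytes. Low depth alone is argued against by c24, whose share was 1.36% although the median total of c34DBF1 was 1.505 times that of c24. Preantral oocytes and c34 had higher median totals (3477839 and 4393084 counts) than c34DBF1 (3105421). No biological explanation was tested, since the labels do not say what sets c34DBF1 apart.

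The amino acid and endoplasmic reticulum stress list stood at 3.02 times the mean of secondary and preantral oocytes in c24, at 1.37 times in c34 and at 2.58 times in c34DBF1. RNA of granulosa cells is argued against, because Foxl2, Kitl, Hsd17b1 and Amhr2 reached at most 3.547% of their preantral granulosa level (Foxl2 in c24), while the list would have needed 636.6% of granulosa RNA in c24 and 496.7% in c34DBF1. For c34DBF1, the bulk libraries of series MS378 held 0.925 (c7) and 0.955 (c11) of the list total of the other library. That argues against a rise in all libraries of the series. It does not decide on its single cells, since no library series holds both c34DBF1 cells and secondary or preantral oocytes. For c24 and c34 the series cannot be told apart from the culture, because 0 library series hold both such cells and secondary or preantral oocytes. Culture itself stays open as an untested biological difference.

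Among 104 sets of 4 to 10 libraries, 18 had a library far from the others. Chance alone gives about 1 in 20 sets, or 5.2, a rate that does not hold for values near the floor such as the 7 sums of red blood cell genes among the 18. The other 11 were still more than 5.2. The total of c34 replicate 1, the library of series MS330, was 2891368 counts against 4327373 to 4831677 in the other c34 cells. In c34DBF1 replicate 4 there were 14062 genes detected against 15079 to 15595. The mitochondrial share was 3.96% in secondary oocyte 3 (others up to 2.7%) and 1.1% in GV oocyte 4 (others up to 0.748%). Summed CPM of the granulosa list was 61.4 in primordial oocyte 6 (others up to 30.02), 242 in primary oocyte 6 (up to 99.7), 620 (619.84) in GV oocyte 5 (up to 577) and 12188 in primordial granulosa pool 6 (up to 7525). The stroma and fibroblast list summed to 4776 CPM in primordial granulosa pool 1 (others up to 2050.0) and to 2365 in preantral granulosa pool 1 (up to 899), which also held 13147 CPM of the immediate early and heat shock list (up to 5932). Red blood cell genes summed to 2.18 CPM in primordial granulosa pool 4, 0.360 in primary granulosa pool 8, 3.75 in secondary granulosa pool 10, 0.376 in preantral oocyte 3, 2.41 in preantral granulosa pool 6, 0.244 in MII oocyte 3 and 0.455 in c34 cell 6, levels close to the floor.

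The stage change differed between oocytes and granulosa cells for 1995 genes. Zglp1, which codes for a factor of the oogenic program under BMP signals, was at 41.7 CPM in c5, a group outside every comparison. Its level was 0.415 in ESC and 5.20 in EpiLC (mean CPM, n = 2 bulk samples per group). The libraries of c5 belong to another library series than those of ESC and EpiLC, so batch and group cannot be told apart.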

How the results depend on the processing

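Leaving out each replicate in turn and the main alternatives were planned, while the comparisons for single days of retinoic acid and for the difference in stage change, their alternatives, and the fits of oocyte or granulosa sums alone were chosen only after the results were seen. In most comparisons the naming rule required no overlap between replicates, so leaving out 1 replicate could hardly reverse a direction. Of 267 named gene values, 3198 recomputed values kept their direction, with 0 reversed. Of these 2805 stayed past the threshold and 393 did not, 327 of the latter among 1580 values with 1 replicate left out. Mitochondrial genes left out moved no count by more than 1.5 times. Replicate numbers do not pair the bulk samples (66 pairs of groups, r from -0.16 to 0.17), and with that number as a block the culture counts were 3267 for EpiLC against ESC, 5602, 4654, 6370 and 4135 for the following steps, 850.0 for extended retinoic acid and 3251 at day 13.

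Without a filter on low counts the counts were about 1.3e+02 for the difference between days, 112, 461 and 403 for retinoic acid at days 7, 9 and 11, 693, 853 and 240 for the 3 oocyte steps in order, and 1343 for granulosa cells. DESeq2's Wald test called 62 genes at day 7, 880.0, 1013 and 263 for the oocyte steps, 1741 for granulosa cells, 3479 for the difference in stage change and 2979 for late culture cells, and its likelihood ratio test 56 for the difference between days. Of the genes called by edgeR in the oocyte steps, 142, 339 and 2 were shared with DESeq2. DESeq2 size factors gave 4 genes for preantral against secondary oocytes, and thinning gave 22. Without series MS378 the counts were 379 for extended retinoic acid, 13 for the difference between days, 5 at day 7 and 72 at day 11. Late culture cells differed in 838 genes from primary to preantral oocytes and in 654 from preantral and antral oocytes. With each pool as a replicate granulosa cells gave 781 genes, of which 286 were shared. Oocyte sums fitted alone with edgeR gave 235 and 616 genes for the first steps, and 0 for preantral against secondary oocytes, with 1874 genes at an unadjusted p under 0.05 and 263 called by DESeq2 in the joint design. Without genes shared between lists, 6 lists instead of 11 were called for the difference in stage change. Genes named by size that stayed with no minimum CPM numbered 3 for antral, 0 for GV, 10 for cumulus, 4 for c34 and 4 for c34DBF1, since rarer genes then took the places, and 10 stayed for MII with a pseudocount of 5. The cause was not tested for the counts that moved, apart from fewer samples or other genes entering by construction.

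Leaving out 1 replicate gave 1955 to 2778 genes for EpiLC, 3990 to 4752 for c3, 2904 to 3409 for c7, 4003 to 5517 for c11, 2443 to 3654 for c13SChigh and 1476 to 2817 for RAc13. For extended retinoic acid the range was 457 to 978, for its difference between days 5 to 59, and at days 7, 9 and 11 it was 5 to 9, 25 to 399 and 52 to 151. Without 1 sum the ranges were 27 to 1535, 11 to 199 and 0 to 4 for the oocyte steps in order, 244 to 862 for granulosa cells, 8823 to 9915 for oocytes against granulosa cells, 965 to 2722 for the difference in stage change and 338 to 1308 for late culture cells. In these fits the lone sample of a group is assumed to vary like the other groups. Depth limits rare genes most, since a floor of 3 counts in the smallest library of 972239 counts is about 3 CPM.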

Other observations

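The tests of other splits below were chosen only after the result was seen.

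Cholesterol synthesis genes changed direction between steps of the culture. EpiLC and c3 differ in library series, and c11 and c13SChigh in sorting, so these cannot be told apart from the step itself. After their rise from ESC to EpiLC, 18 of 19 fell in c3 with 0 higher (18 and 0 adjusted over the list alone), and Fdps, which codes for a farnesyl diphosphate synthase, fell by 2.62 ± 0.18 (fry's adjusted p = 9.4e-08). From c7 to c11 another 17 of 19 fell with 0 higher (17 and 0 adjusted over the list alone), and Srebf2, the gene of their main regulator, fell by 2.86 ± 0.26 (fry's adjusted p = 3.3e-07). In c13SChigh 8 of 19 were higher than in c11 and 0 lower (9 and 0 adjusted over the list alone), for example Fdft1 by 2.09 ± 0.20 (fry's adjusted p = 0.00048).

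Ldhb, the lactate dehydrogenase gene that prevails in oocytes, stood at 331 CPM in c7 and 38.2 in c11, a log2 change of -3.13 ± 0.20, and rose by 4.48 ± 0.20 to 844 CPM in c13SChigh. Glycolysis genes fell in 7 of 19 cases and rose in 1 from c7 to c11 (7 and 1 adjusted over the list alone), and rose in 8 and fell in 2 from c11 to c13SChigh (8 and 2 adjusted over the list alone). The class II antigen gene H2-Ab1 rose by 2.77 ± 0.23 from c7 to c11 and fell by 2.89 ± 0.25 in c13SChigh. The keratin gene Krt18 was lower in c13SChigh than in c11 (-3.81 ± 0.49), in a list of somatic lineages with 3 of 10 lower and 0 higher (3 and 0 adjusted over the list alone). Cells at c11 were not sorted by the gate of c13SChigh, so sorting and day cannot be told apart for these genes.

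The median of a list and the direction of its test differed in sign in a few called lists beside those given above. From EpiLC to c3 the DNA methylation list had a median of 0.01 and was called lower, and the granulosa list had -0.05 and was called higher. From c7 to c11 the oocyte maturation list had a median of 0.24 and was called lower, and the immune list had -1.10 and was called higher.

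Other splits of the same sums were counted for the broad comparisons. For late culture cells against secondary and preantral oocytes, 1 of 35 splits, the real one, reached 1460 genes, and the highest other gave 0 genes by edgeR. Every other split mixes cultured and in vivo sums, which puts their difference into the spread and lowers the count. A difference between library series alone would give the same result, so these splits do not decide what made the difference. For oocytes against granulosa cells, 1 of 40 splits within stages reached 9765 genes, and the highest other gave 6096. Splits that mix the cell types in part thus also called many genes, so the number of splits says little about chance there.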
